A study of Anas platyrhynchos with 11 samples.

How the data were processed

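RNA was measured in 5 samples of hand-collected Meissner corpuscles and 6 of bill skin. Per the labels' protocols, a pipette took 2 to 10 corpuscles, corpuscle RNA was at 63 to 323 pg/µl with integrity numbers of 6.1 to 8.0, and different library kits were used for the 2 tissues. Read counts per gene were deposited by the authors as whole numbers, not normalized. Per the submitters' processing notes the tools were CASAVA 1.8.2, Trimmomatic 0.39, STAR 2.7.7a, featureCounts, Subread 2.0.1, edgeR 3.38.4 and R 4.2.1; the genome build, the annotation and the use of strand were not given in the sources used here. Normalized counts, a signal per gene, were deposited too, and their values show that each is the count divided by one factor per sample. FPKM values were deposited by the authors and equal that signal per kilobase of one length per gene. The deposited table of the authors also gives a log2 fold change, skin relative to corpuscle, with its p-value and false discovery rate. Total counts per library ran from 5766279 to 20925841.

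The table held 16823 genes, and 147 of them had no count. Of 4214 locus identifiers 3196 matched a RefSeq gene table of the Pekin duck by gene ID and 603 gained a symbol, among them MBP, DSP, CPXM1 and CACNA1S; its coordinates were not used. Gene lengths, from 251 to 103953 bp, were taken from the ratio of normalized count to FPKM. No mitochondrially encoded protein gene of the list fixed for them was in the table, so their share of counts was not analysed here.

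Counts were fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood fit of corpuscle against skin, Benjamini-Hochberg threshold 0.05). Values are given as CPM on TMM-scaled library sizes, with SD over libraries, and log2 fold changes are corpuscle minus skin with SE. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives; 23 of 24 lists had members to test. Library complexity was compared by two-sided exact permutation tests in scipy 1.17.1. At these depths 3 counts equal 0.520 CPM in the smallest library and 0.143 CPM in the largest, and such floors cover counting error only. Replicates differed by more than sampling noise, the lowest chi-square per degree of freedom being 11.6.

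Groups, lists, tests and the rule for named genes were set before the data were examined. The rule names fixed genes of Schwann cells and channels, up to 3 called members per list by fold without overlap between tissues (at least 10 CPM, or 1 CPM for channels and receptors), the 8 highest and 8 lowest at 50 CPM or more, and the 2 most abundant of each channel or receptor list. Genes outside the rule are said in the text to have been named after their values were seen. Of the fixed genes, S100B and CACNA1A were not analysed here, and some genes that the rule names are not reported here. The fit was tested on simulated data for the comparison of corpuscle with skin, over 14638 genes. It recovered 66% of 100 genes changed 4-fold and 7% of 100 genes changed 2-fold, with 5 false calls among 78, and called both planted lists. Genes were drawn independently, with the same dispersion in both tissues. The gene test changed 200 genes, while 8263 were called in the real data. Recovery at the real share of changed genes, and camera under correlation within lists, were therefore not tested.

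The authors' deposited table calls 9920 of its genes at the same threshold, without a filter on low counts, 6177 of them higher and 3743 lower in corpuscles. Of the genes called here, 8078 had the same direction and a false discovery rate under the threshold in the authors' deposited table, 185 were not called there and 0 were called in the opposite direction.

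Alternatives fixed in advance were other scalings, filters, DESeq2 1.42.0, limma-voom, a replicate block with and without a length correction, thinning to the smallest library, leaving out the 20 most abundant genes, a test against a fold of 2, and leaving out each library. Added after seeing the data were subtraction of background from corpuscle counts, fits without corpuscles 4 and 5 or skin 5 and 6, and fits within or adjusted for the split on the second principal component. Genes of liver, retina, pituitary and germ cells (71 in the table, on 4 lists written before their values were seen) served as a measure of background. Figures were drawn with matplotlib 3.10.9.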

Results

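Meissner corpuscles are touch end organs in which a sensory axon is enclosed by lamellar cells. In the duck (Anas platyrhynchos) they were aspirated by hand from bill skin and profiled by bulk RNA sequencing, beside skin cells collected nearby that held no corpuscles. There were 5 corpuscle libraries and 6 skin libraries. Total counts ran from 5766279 (corpuscle 4) to 11886808 (corpuscle 3) in corpuscles, and from 13263776 (skin 4) to 20925841 (skin 2) in skin. Every corpuscle library was made with a kit for low input and every skin library with a standard messenger RNA kit, so tissue and kit cannot be told apart in any comparison here. The labels name 3 independent skin isolations without tying libraries to them, so p-values measure only the spread between these libraries.

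Corpuscles differed from bill skin in most of the genes tested. Chromogranin B (CHGB), a protein of secretory granules, was the most abundant of the genes that rose, at 41726 ± 20298 CPM (SD, n = 5) in corpuscles and 1286 ± 323 CPM (n = 6) in skin. Elastin (ELN), the protein of elastic fibres, was among the genes that fell most, at 24.3 ± 15.2 CPM in corpuscles and 1724 ± 505 CPM in skin. Of 14638 genes tested, edgeR's quasi-likelihood test called 8263 at a Benjamini-Hochberg adjusted p of 0.05, with 4826 higher and 3437 lower in corpuscles. By over 2-fold, 4373 were higher and 2924 lower. Of the genes called higher, 2757 (57.1%) lay at or under 8.36 FPKM in corpuscles, the 95th percentile of 71 genes of unrelated organs in the same libraries. In 6040 genes (41.3%) no corpuscle library overlapped any skin library, against 0.433% by chance; of the called genes named below by rule, CACNA1D alone overlapped. The biological coefficient of variation was 64.5% within corpuscles and 24.2% within skin.

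On the second principal component (11.9% of variance) corpuscles 4 and 5 had scores of -124 and -40.9, and skin 5 and 6 of -20.1 and -24.3. The other libraries had positive scores, from 4.45 (skin 2) to 62.1 (corpuscle 1). The split used below follows that sign and does not mark a tight group. Within corpuscles 1 to 3 and skin 1 to 4 the same test called 8005 genes, and within corpuscles 4 and 5 and skin 5 and 6 it called 5290. Of the 23 gene lists tested, camera with a preset correlation called 13, and with an estimated correlation it called 0, with 6 at an unadjusted p under 0.05. Another tool, fry, called 20 and its mixed form 23, but it tests another hypothesis. It asks whether the members of a list change at all, not whether they change more than other genes. With 56.4% of all genes called, those counts say little about any list. With the preset correlation, regroupings of the libraries in which edgeR called no gene gave a median of 5 lists and up to 12. Those regroupings still mix the tissues in unequal shares, so they do not measure false calls.

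**Figure D1:**
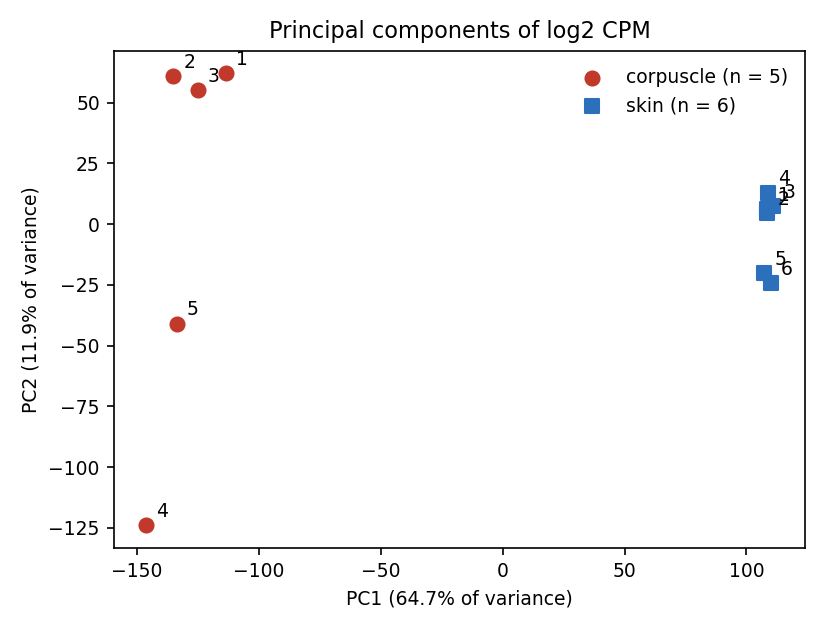
Scores of the 11 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis; circles are corpuscles, squares are skin and numbers are replicates. Component 1 (64.7%) parts the tissues, and component 2 (11.9%) spreads the corpuscle libraries more than the skin libraries.

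Genes of Merkel cells, the neuroendocrine touch cells of skin, were higher in corpuscles. Of the 22 members tested 18 rose and 1 fell, and the counts were the same when adjusted over the list alone. CHGB had a log2 fold change of 5.02 ± 0.38 (SE). KRT20, a keratin of Merkel cells, rose by 4.67 ± 0.64 (4.02 without corpuscle 3), from 147 ± 40.5 CPM in skin to 3736 ± 3540 CPM. SNAP25, a protein of vesicle fusion, rose by 4.99 ± 0.41. Among members picked after their values were seen, the granule proteins CHGA (3.48) and SCG2 (3.89) and the transcription factors ISL1 (3.63), INSM1 (3.14) and ATOH1 (1.65) rose, and the prohormone convertase PCSK2 fell (-2.36). The list's median log2 fold change was 1.97, with a camera adjusted p of 0.000567 at the preset correlation and an adjusted p of 0.104 with an estimated correlation. Of the 18 members that rose, 10 lay above the level of genes of unrelated organs.

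Sensory neuron and axon genes were also higher as a list, with 15 of 24 rising and 3 falling (15 and 4 when adjusted over the list alone). Of those that rose, SNAP25 is also on the Merkel and synaptic vesicle lists. Named after their values were seen, ISL1 is shared with the Merkel list and SYT1 with the synaptic list. RAB3C and SYT7, named likewise, rose on both of those lists, so these lists are not independent. STMN2, a microtubule regulator of growing axons, rose by 4.30 ± 0.70 on the log2 scale (3.64 without corpuscle 3). UCHL1, a neuronal deubiquitinase, rose by 3.76 ± 0.40, to 672 ± 416 CPM from 49.5 ± 13.7 CPM. Named after their values were seen, the neurofilament genes NEFH (log2 fold change -0.68) and NEFM (0.49) did not pass the test, while NEFL (1.92) and the microtubule gene MAP1B (1.14) rose, and CNTN1, MAPT and PRPH fell. At or under the level of genes of unrelated organs lay 6 of the 15 that rose. The camera adjusted p was 0.0253, and the adjusted p was 0.218 with an estimated correlation. It was 0.162 within corpuscles 4 and 5 and skin 5 and 6, and 0.0585 with limma-voom.

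For synaptic vesicle and release genes 21 of 37 rose and 1 fell (DNM1, named after its value was seen), also when adjusted over the list alone. SV2B, a vesicle membrane protein, rose by 4.58 ± 0.31, to 283 ± 136 CPM from 11.9 ± 1.37 CPM. ERC2, of the presynaptic active zone, rose by 3.51 ± 0.48. The camera adjusted p was 0.00129, and the adjusted p was 0.0853 with an estimated correlation. Of the 21 that rose, 13 lay at or under the level of genes of unrelated organs.

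Schwann cell and glial genes moved both ways. Of 21 tested, 5 rose and 8 fell, over all genes and adjusted over the list alone, with a median log2 fold change of -0.24 and a camera adjusted p of 0.202 (0.0367 within corpuscles 4 and 5 and skin 5 and 6). PRX (periaxin), a myelin protein, was at 1.8 ± 0.819 CPM in corpuscles and 37.7 ± 10.7 CPM in skin, a log2 fold change of -4.40 ± 0.43. MBP was at 128 ± 228 CPM in corpuscles and 1170 ± 353 CPM in skin (-3.19 ± 1.06, adjusted p = 0.022), with corpuscle 3 at 534 CPM. Without corpuscle 3 the log2 fold change of MBP was -5.49, and without corpuscles 4 and 5 it did not pass (-2.58, adjusted p = 0.0529). SOX10, a transcription factor of Schwann cells, was at 241 ± 129 CPM and 153 ± 20.6 CPM and did not pass (0.66 ± 0.32, adjusted p = 0.0873). It passed without corpuscle 3 (adjusted p = 0.0233), without corpuscle 4 (adjusted p = 0.0153), with upper-quartile factors (adjusted p = 0.0384), and under 4 other alternatives (adjusted p from 0.0224 to 0.0369). PMP22, another myelin gene and named after its value was seen, was at 724 and 853 CPM and did not pass (-0.24, adjusted p = 0.335). The members that rose included TFAP2A and, named after their values were seen, ARTN, CDH2 and GAP43. At or under the level of genes of unrelated organs lay 3 of the 5 that rose, among them ARTN (1.05 FPKM) and GAP43 (0.58 FPKM).

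Neural crest genes gave 7 higher and 4 lower of 21 (6 and 4 adjusted over the list alone; camera adjusted p = 0.775). The transcription factors TFAP2A and TFAP2B rose by 2.32 ± 0.23 and 2.46 ± 0.22, and ETS1 by 0.75 ± 0.21 (not passing within corpuscles 4 and 5 and skin 5 and 6, adjusted p = 0.231). Named after their values were seen, EDNRB, ERBB3, MSX1 and TWIST1 fell.

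**Figure D2:**
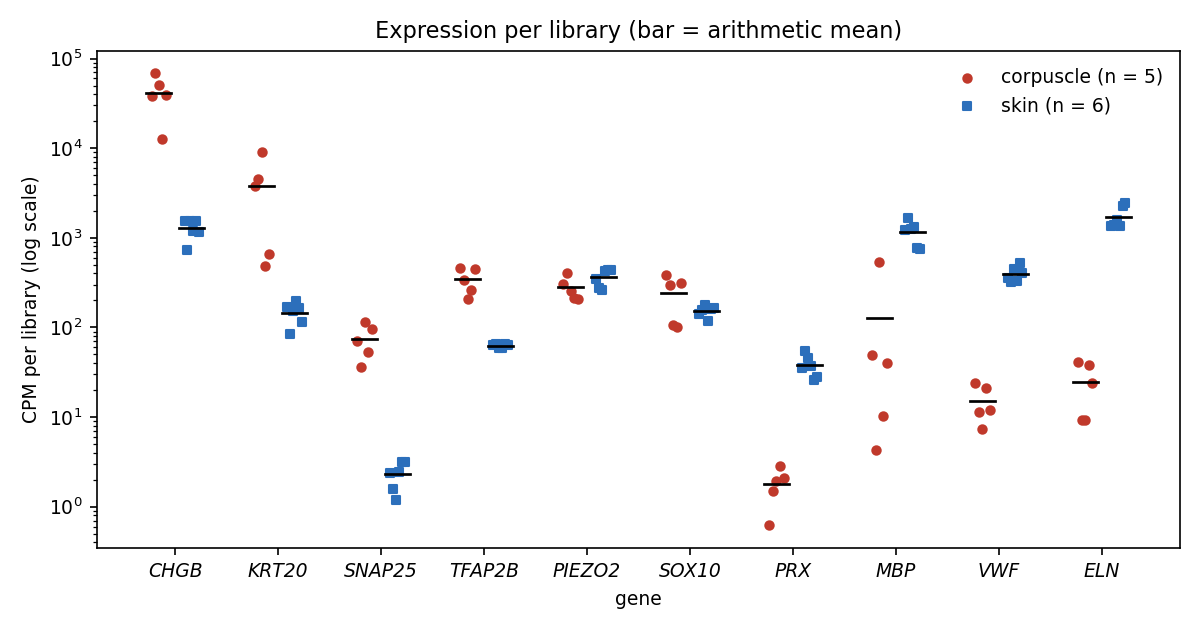
CPM of 10 genes in each library on a log scale, circles for the 5 corpuscle libraries, squares for the 6 skin libraries and bars for arithmetic means. CHGB, KRT20, SNAP25 and TFAP2B stand higher in every corpuscle library, PRX, MBP, VWF and ELN lower, and PIEZO2 and SOX10 overlap.

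PIEZO2, the mechanically gated channel of touch receptors, was the second most abundant of the 28 mechanosensitive genes in corpuscles and did not pass the test. It was at 279 ± 82.2 CPM in corpuscles and 365 ± 81.0 CPM in skin (log2 fold change -0.39 ± 0.22, adjusted p = 0.155); it passed without corpuscle 2 (-0.57, adjusted p = 0.0361) and within corpuscles 4 and 5 and skin 5 and 6 (-0.99, adjusted p = 0.0437). PIEZO1 fell (log2 fold change -1.51 ± 0.36), from 48.6 ± 10.5 CPM in skin to 17.2 ± 9.29 CPM, but did not pass within corpuscles 4 and 5 and skin 5 and 6 (-0.55, adjusted p = 0.357). STOM (stomatin), a membrane protein that binds ion channels, rose by 2.06 ± 0.22, to 302 ± 72.3 CPM from 72.6 ± 18.5 CPM. TRPA1 and TMC2 rose by 7.03 ± 0.87 and 4.19 ± 0.76, to 6.72 and 3.81 CPM, against 4 and 19 reads over all skin libraries. Without corpuscle 4 the values were 6.34 for TRPA1 and 3.28 for TMC2, and without skin 1 that of TRPA1 was 7.65. In all, 9 members rose and 7 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.900). Of the 9 that rose, 7 lay at or under the level of genes of unrelated organs, among them TRPA1 (1.55 FPKM) and TMC2 (1.29 FPKM). The list's median log2 fold change was -0.05 and its mean 0.60; camera gave a downward and fry an upward direction.

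Of 19 voltage-gated calcium channel genes 10 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.145). CACNA1B, of the N-type channel of nerve terminals, rose by 3.03 ± 0.49 to 46.1 ± 32.8 CPM, and CACNA1H, of a T-type channel, by 2.32 ± 0.32. CACNA1S, of the channel of skeletal muscle, rose by 6.22 ± 0.75 (7.35 without skin 2), against 20 reads over all skin libraries. CACNA1D rose by 1.32 ± 0.45 and lost its call without corpuscle 1 (0.94, adjusted p = 0.0853) and under 5 other alternatives (0.94 to 1.45, adjusted p from 0.0629 to 0.163). CACNA1G and CACNA1C fell (log2 fold changes -1.68 ± 0.31 and -1.52 ± 0.35) but did not pass within corpuscles 4 and 5 and skin 5 and 6 (-1.61 and -0.68, adjusted p = 0.103 and 0.221). CACNA1E, of the R-type channel, was at 30.8 ± 14.7 and 32.7 ± 6.49 CPM (-0.09 ± 0.32, adjusted p = 0.834), and its sign turned with upper-quartile factors (0.046). CACNB4, a channel subunit, did not pass (-1.24 ± 0.87), but did within corpuscles 4 and 5 and skin 5 and 6 (-5.02, adjusted p = 0.0177). In skin it was at 275 to 278 CPM in skin 2, 5 and 6 and at 23.3 to 34.6 CPM in skin 1, 3 and 4. In corpuscles it was at 86.8 to 123 CPM in corpuscles 1 to 3, and at 9.51 and 7.03 CPM in corpuscles 4 and 5. Its skin values thus did not follow the split, since skin 2 was as high as skin 5 and 6. Sodium channel genes gave 3 higher (among them SCN4A and, named after its value was seen, SCN4B) and 0 lower of 7, by edgeR, also adjusted over the list alone (camera adjusted p = 0.39). SCN4A, of the channel of skeletal muscle, rose by 1.45 ± 0.34 and lost its call after background subtraction (0.85, adjusted p = 0.0976), while NALCN and SCN8A (37.7 ± 13.5 against 56.4 ± 7.27 CPM) did not pass; SCN8A did without corpuscle 1 (adjusted p = 0.0230) and with limma-voom (adjusted p = 0.0476), and NALCN without corpuscles 4 and 5 (0.72, adjusted p = 0.0246). All 10 calcium and 3 sodium channel genes that rose lay at or under the level of genes of unrelated organs.

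Potassium channel genes were higher in corpuscles, with 33 of 55 rising and 5 falling (34 and 5 adjusted over the list alone) and a median log2 fold change of 1.75. KCND2, of the A-type current of neurons, rose by 4.58 ± 0.52 to 135 ± 78.9 CPM (within corpuscles 4 and 5 and skin 5 and 6 3.39, not passing, adjusted p = 0.0844), and KCNJ2, an inward rectifier, by 2.31 ± 0.26 to 90.7 ± 20.3 CPM. KCNJ6 rose by 8.89 ± 0.81 (9.79 without skin 2) to 32.7 ± 21.5 CPM, against 6 reads over all skin libraries, and lay under the level of genes of unrelated organs (3.61 FPKM). The members that fell, named after their values were seen, were KCNJ8, KCNJ15, KCNMB1, KCNN1 and KCNV1. The camera adjusted p was 0.00196, and the adjusted p was 0.172 with an estimated correlation. At or under the level of genes of unrelated organs lay 25 of the 33 that rose. After subtraction of a background set by gene length the adjusted p was 0.0832, in a range over the camera alternatives of 0.0002 to 0.172.

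Among the 56 neurotransmitter receptor genes 37 rose and 4 fell (39 and 5 adjusted over the list alone), with a median log2 fold change of 2.40. Levels were low, with a median of 6.68 CPM in corpuscles and 1.07 CPM in skin. GRIA2, an AMPA receptor subunit, rose by 1.47 ± 0.31 to 42.7 ± 17.2 CPM, but did not pass within corpuscles 4 and 5 and skin 5 and 6 (0.81, adjusted p = 0.313). The most abundant member, CHRNA10, did not pass (58.8 ± 29.6 against 33.0 ± 9.36 CPM, adjusted p = 0.0556), but did without corpuscle 3 (adjusted p = 0.0462), corpuscle 4 (0.00923) or skin 1 (0.0481), and under 8 other alternatives (adjusted p from 0.00553 to 0.0420). Named after their values were seen, GABBR1, P2RX4, P2RX7 and P2RY1 fell. The camera adjusted p was 1.8e-05 and the adjusted p with an estimated correlation was 0.228. All 37 that rose lay at or under the level of genes of unrelated organs. The call was lost after background subtraction (adjusted p = 0.205) and with a minimum of 5 CPM (0.308), in a range over the camera alternatives of 1.05e-06 to 0.308.

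**Figure D3:**
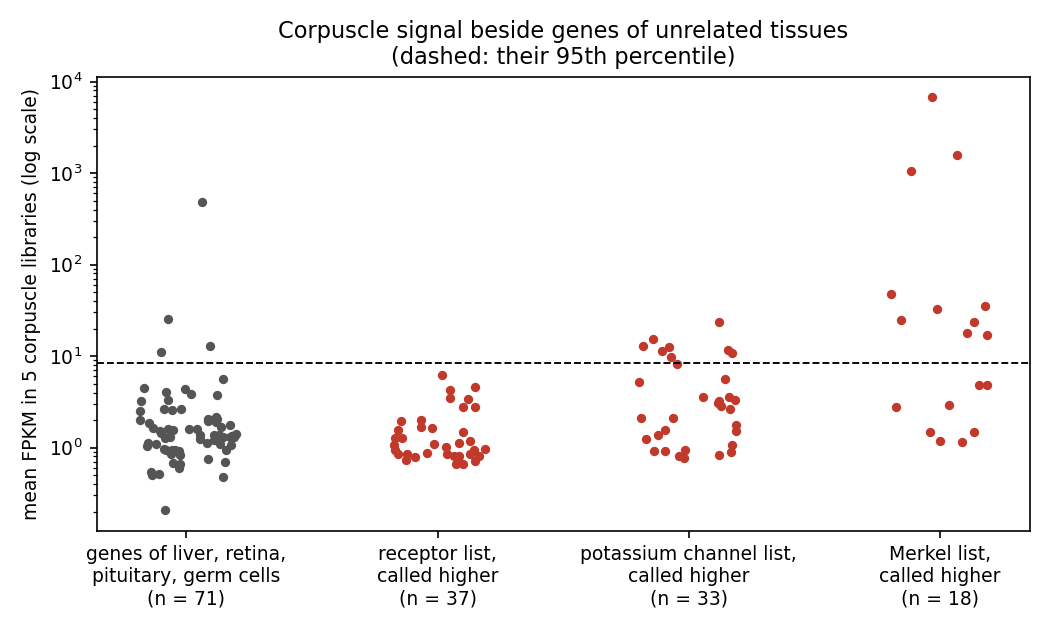
Mean FPKM in the 5 corpuscle libraries, on a log scale, of 71 genes of unrelated organs and of the members called higher on the receptor, potassium channel and Merkel lists; the dashed line is the 95th percentile of the first set (8.36 FPKM). All 37 receptor genes lie under it, and 10 of the 18 Merkel cell genes lie above it.

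Genes of vessels and dermis were lower in corpuscles. Endothelial genes had the lowest median log2 fold change of the 23 lists, -2.64, with 21 of 25 falling and 1 rising, also adjusted over the list alone. CDH5, a cadherin of vessel walls, had a log2 fold change of -4.75 ± 0.43, VWF of -4.72 ± 0.33 and PECAM1 of -4.44 ± 0.46. PROX1, a transcription factor of lymphatic vessels named after its value was seen, rose but lay under the level of genes of unrelated organs (6.04 FPKM). Fibroblast and dermal matrix genes gave 24 lower and 1 higher of 31 (25 and 1 adjusted over the list alone). MFAP5 (-4.19 ± 0.28), COL14A1 (-3.63 ± 0.37) and FBN1 (-3.00 ± 0.21), of fibrils and elastic fibres, fell, and COL5A1, a fibrillar collagen named after its value was seen, rose (1.66). Camera adjusted p-values were 2.62e-10 for endothelium and 2.3e-09 for fibroblasts, and adjusted p-values with an estimated correlation were 0.101 and 0.173.

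Basement membrane genes gave 16 lower and 4 higher of 27, also adjusted over the list alone. HSPG2 (perlecan) had a log2 fold change of -4.24 ± 0.23, LAMA3 of -3.71 ± 0.39 and LAMA2 of -2.80 ± 0.27. Those that rose included, named after their values were seen, COL4A3, FREM2 and LAMC1. At or under the level of genes of unrelated organs lay 3 of the 4 that rose (not LAMC1). Camera gave an adjusted p of 8.81e-05, and the adjusted p was 0.101 with an estimated correlation. Junction genes gave 14 lower and 7 higher of 29, also adjusted over the list alone. CTNND1 (-3.18 ± 0.25) and CLDN19 (-3.24 ± 0.46) fell. Their camera adjusted p was 0.00427, and the adjusted p was 0.0748 with an estimated correlation.

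Of 22 keratinocyte genes tested 9 fell and 3 rose, also adjusted over the list alone. The list held 44 genes, and those missing from the table included KRT5, KRT14, KRT10, DSG1, IVL and LOR. DSP and PKP1, of desmosomes, had log2 fold changes of -4.10 ± 0.49 and -3.42 ± 0.46, and SFN of -3.01 ± 0.65. CDH3, GRHL3 and SCEL, named after their values were seen, rose, and 2 of these 3 (not CDH3) lay at or under the level of genes of unrelated organs. The camera adjusted p was 0.0355 and the adjusted p with an estimated correlation 0.461. It was 0.0700 without corpuscle 4 and 0.0504 without skin 3, in a range over the camera alternatives of 0.0112 to 0.461. Muscle and pericyte genes went both ways, with 8 lower and 5 higher of 16 (9 and 5 adjusted over the list alone; camera adjusted p = 0.202). Their median log2 fold change was -1.40, but 0.77 within corpuscles 4 and 5 and skin 5 and 6, with 4 lower and 9 higher of 19. ACTA2, the smooth muscle actin (-4.99 ± 0.41), MYH11 (-3.11 ± 0.49) and TAGLN (-2.96 ± 0.53) fell, MYH11 not passing within corpuscles 4 and 5 and skin 5 and 6 (-1.55, adjusted p = 0.118). Named after their values were seen, TTN (4.35) and NEB (3.09), of skeletal sarcomeres, ACTA1, TNNT3 and MYLK rose; 4 of these 5 lay at or under the level of genes of unrelated organs.

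**Figure D4:**
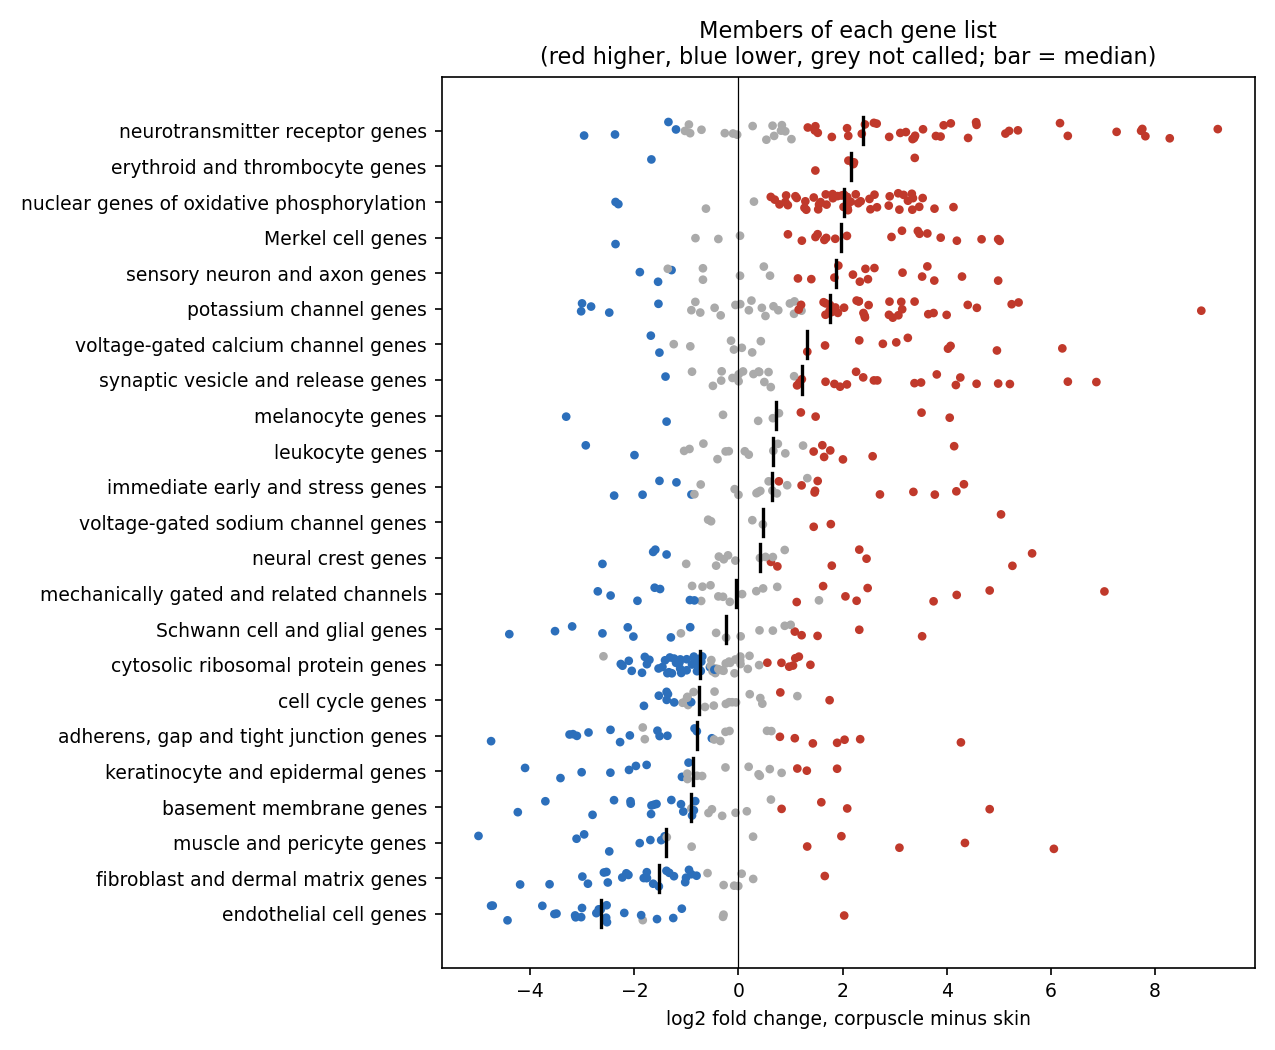
Log2 fold change (corpuscle minus skin) of each tested member of 23 gene lists, each point a gene, red where called higher, blue where called lower, grey where not called, with a bar at the list's median. Endothelial genes have the lowest median (-2.64) and receptor genes the highest (2.40).

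Nuclear genes of oxidative phosphorylation rose nearly throughout the list, with 48 of 52 higher and 2 lower, also adjusted over the list alone, and a median log2 fold change of 2.03. The complex I subunits NDUFA2, NDUFB4 and NDUFS6 rose by 4.13 ± 0.25, 3.77 ± 0.21 and 3.54 ± 0.26; NDUFA2 went from 14.9 ± 2.11 CPM to 261 ± 75.8 CPM. NDUFS3 (-2.36), also of complex I and named after its value was seen, was among those that fell. Camera gave an adjusted p of 1.01e-19, and the adjusted p was 0.0587 with an estimated correlation. Lists of other genes matched on length and abundance had a median of 1.49.

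Cytosolic ribosomal protein genes went the other way, with 37 of 64 lower and 7 higher (38 and 7 adjusted over the list alone) and a median log2 fold change of -0.73. With the length correction 52 were lower and 2 higher, with a median of -1.27. RPL9, RPL12 and RPS2 had log2 fold changes of -2.26 ± 0.23, -2.23 ± 0.19 and -2.11 ± 0.25. The camera adjusted p was 1.8e-05, and the adjusted p was 0.562 with an estimated correlation.

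Immediate early and stress genes gave 10 higher and 5 lower of 27 (11 and 5 adjusted over the list alone; camera adjusted p = 0.223). The list passed with a minimum of 5 CPM (adjusted p = 0.0245) and after background subtraction (0.0318), in a range over the camera alternatives of 0.0245 to 0.968. The transcription factors FOS, FOSB and NR4A3 rose by 3.77 ± 0.54, 4.33 ± 0.62 and 4.19 ± 0.32, FOS not passing within corpuscles 4 and 5 and skin 5 and 6 (2.08, adjusted p = 0.128). Named after their values were seen, BAG3, BTG2, EGR1, IER5 and KLF2 fell. Cell cycle genes gave 7 lower and 2 higher of 26, also adjusted over the list alone. CCNE2 (-1.82 ± 0.38), KIF23 (-1.38 ± 0.37) and TPX2 (-1.23 ± 0.37) fell, but did not pass within corpuscles 4 and 5 and skin 5 and 6 (-0.95, -1.10 and -1.59, adjusted p = 0.197, 0.293 and 0.241), nor TPX2 after background subtraction (-1.11, adjusted p = 0.0603). MKI67 and UBE2C, named after their values were seen, rose. The list's camera adjusted p was 0.0407, and the adjusted p was 0.531 with an estimated correlation. It was 0.125 without corpuscle 4, 0.0503 without skin 2, 0.0631 without skin 4 and 0.0552 without skin 5, in a range over the camera alternatives of 0.00148 to 0.531.

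Leukocyte genes gave 7 higher and 2 lower of 21 (camera adjusted p = 0.900), CD4, a T cell coreceptor, rising by 4.14 ± 0.65 (3.28 without corpuscle 3) but not passing within corpuscles 4 and 5 and skin 5 and 6 (2.07, adjusted p = 0.159). Their median log2 fold change was 0.67, while camera gave a downward and fry an upward direction. Without corpuscles 4 and 5 there were 5 higher and 7 lower, with a median of -0.31. Erythroid and thrombocyte genes gave 5 higher and 1 lower of 6 (camera adjusted p = 0.202, or 0.0277 within corpuscles 4 and 5 and skin 5 and 6), ANK1 and SPTB, of the red cell skeleton, rising by 2.21 ± 0.46 and 2.11 ± 0.46. Of the 23 genes on that list 8 were in the table, without ALAS2, GATA1 or any of its globin genes. Melanocyte genes gave 4 higher and 2 lower of 10 (camera adjusted p = 0.900), OCA2, a melanosome protein, rising by 4.06 ± 0.58. Counts adjusted over the list alone were the same for each of these lists. At or under the level of genes of unrelated organs lay 6 of the 7 leukocyte genes that rose (not CD4), all 5 erythroid and thrombocyte genes and 3 of the 4 melanocyte genes, OCA2 among them. Named after their values were seen, CD74, MRC1, TAL1, EDNRB and KIT fell, and ITGA2B, RHAG, TUBB1, DCT, GPR143 and SLC24A5 rose.

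Of genes with a symbol and at least 50 CPM, those that rose most included RAB44 (6.66 ± 0.53), CBLN2 (6.30 ± 0.71) and GNG13 (6.17 ± 0.52), and also SNTN, ATP6V0E2 and S100A16. CBLN2 encodes a secreted synaptic organizer. S100A16, a calcium-binding protein, was at 752 ± 253 CPM in corpuscles and 18.1 ± 3.12 CPM in skin. Those that fell most were CCN3 (-8.20 ± 0.38, 1.74 ± 0.778 against 502 ± 137 CPM), COCH (-7.16 ± 0.43), COL16A1 (-6.80 ± 0.42) and CPXM1 (-6.46 ± 0.47), then ELN, CHD3, APOA1 and FAAP100; a bias by GC content was not tested.

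Corpuscle libraries held more genes at low levels and gave a larger share of counts to a few genes. The 10 most abundant genes took 12.4 ± 1.54% of counts in corpuscles (n = 5) and 9.76 ± 1.25% in skin (n = 6), a difference of 2.61 percentage points (two-sided exact permutation test, p = 0.0173). Genes with at least 1 CPM numbered 14639 ± 698 and 12720 ± 106, a difference of 1919 (exact permutation p = 0.00433). At a minimum of 5 CPM the numbers were 10899 ± 949 and 10819 ± 116 (exact permutation p = 0.909).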

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

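The tests of background by subtraction and at lower percentiles, of matched lists and of corpuscle transcripts in skin were chosen after the results were seen, as were the bounds for the correction for gene length; that correction, the comparison with the 95th percentile of genes of unrelated organs and the regrouping of libraries were fixed before. Among 195 groups of libraries 19 values stood apart from their group by Dixon's criterion, and chance gives about 1 in 20; 18 of them are given here.

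In corpuscles, MBP was at 534 CPM in corpuscle 3 and from 4.24 to 49.4 CPM in the others, and CACNA1B at 102 CPM in corpuscle 2 (16.5 to 41.3 CPM in the others). Corpuscle 4 held TMC2 at 11.1 CPM (1.11 to 3.60 CPM in the others) and a total count of 5766279, the smallest of its group. In skin 3, APOA1 was at 232 CPM, CACNA1D at 17.2 CPM, MFAP5 at 239 CPM and TAGLN at 24.8 CPM, each the highest of its group. In skin 4, CHD3 was lowest at 119 CPM, and KCNH1 (0.607 CPM) and STOM (109 CPM) were highest. Skin 1 had the lowest PECAM1 (263 CPM) and the highest RAB44 (1.6 CPM), SCN8A (70.4 CPM) and TFAP2A (57.7 CPM). Skin 2 had the highest CACNA1S (0.630 CPM) and the highest total count, 20925841, and skin 5 the highest FOSB (2.32 CPM).

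Receptor and potassium channel genes were higher in corpuscles at low levels, beside a low signal there from genes of unrelated organs: 70 of 71 such genes had a read in every corpuscle library and 44 in every skin library, at a median of 1.37 and 0.127 FPKM. For the receptor list, subtraction left 42 of 56 members to test, with 18 higher and 6 lower. Their median log2 fold change was 1.05 (camera adjusted p = 0.2046), against 2.40 over all 56 in the main fit. Counts were lowered in corpuscle libraries only, so some fall was built in. The level subtracted was the median of 934 genes picked for having no read in skin, 0.206 to 1.07 FPKM per corpuscle library. In every corpuscle library it lay under the median of genes of unrelated organs, which ran from 0.696 to 2.45 FPKM. Background reads may be a cause, since 100% of the members that rose lay at or under the 95th percentile of genes of unrelated organs. Low expression in corpuscles would look alike. That percentile is set high by a few genes, and 12 of the 71 exceed 1 FPKM in skin; at the 75th percentile 30 of the 37 receptor genes lay under it, and at the median 24. For the potassium channel list 75.8% of the 33 that rose lay under the 95th percentile, 13 under the 75th percentile and 9 under the median. Subtraction left 52 of 55 members to test, with 23 higher and 7 lower and a median of 1.31 (camera adjusted p = 0.0832). It is left open how far background or expression in corpuscles gave that list's call. For the Merkel list 44.4% lay under the 95th percentile, between the bounds set in advance (4 of 18 under the 75th percentile, 2 under the median). At the preset correlation the list kept its call after subtraction (camera adjusted p = 0.000124). With an estimated correlation, before subtraction, the camera adjusted p was 0.104. The kept call argues only against background at the subtracted level as the whole cause, at the preset correlation. Background at the higher level of genes of unrelated organs was not subtracted, so that level was not tested.

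Nuclear genes of oxidative phosphorylation were higher in corpuscles by a median of 2.03 on the log2 scale. Correction for each library's trend with gene length left a median of 1.54, and ribosomal protein genes, also short, fell, which argues against length as the whole cause. Lists of other genes matched on length and abundance had a median of 1.49, which is most of the rise, although ribosomal protein genes were at -0.73 against 1.89 for lists matched to them (0.60 with their own members in the pool); the oxidative phosphorylation list lay at percentile 99.1 of 10000 such lists, but at 97.0 when its own members were left in the pool, so a trend shared by many, not all, short and abundant transcripts stays open. Library kit and RNA amount cannot be told apart from tissue, because 0 of the groups had libraries from both kits. A difference between the tissues themselves is a further open explanation.

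Transcripts abundant in corpuscles were also read in skin, CHGB at 3.08% of its corpuscle level. Cells like those of corpuscles within the skin samples may be a source: the 20 most abundant corpuscle-enriched genes varied together over the 6 skin libraries, with a mean correlation of 0.336, at percentile 99.99 of 10000 sets matched on skin expression. Reads of corpuscle libraries assigned to skin libraries would give every abundant corpuscle gene at least the same share, and 4 genes above 100 CPM in corpuscles had far lower shares, such as 1.39% for GNG13, which argues against that as the whole cause. Expression of these genes by other cells of the skin was not tested.

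For the number of genes called, the real grouping gave 8263, and of 100 groupings of the libraries into 5 and 6, drawn from 462, 1 gave as many, the real one; the highest of the others gave 5238. By over 2-fold it was again 1 of 100, with 7297 and 4916. In both cases that share was under 0.05, with libraries taken as exchangeable units. The labels do not tie libraries to the 3 independent skin isolations, so chance differences between isolations were not excluded. The highest other grouping set 5 skin libraries against the 5 corpuscle libraries and the skin library left over, which nearly repeats the real one. For lists called by camera with a preset correlation it was 3 of 100, with 13 and 13, a share under 0.05. That count of lists says little by itself: 93 groupings in which edgeR called no gene gave a median of 5 lists and up to 12. Those groupings still mix the tissues in unequal shares, so they do not measure false calls. With 1 corpuscle library in the group of 5 they gave 7 to 12 lists, with 3 they gave 3 to 12, and with 4 they gave 10 to 12. With 2, the most even mix of the tissues, they gave 0 to 9. At the preset correlation camera thus called lists near an even mix in which edgeR called no gene.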

How the results depend on the processing

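The fits with background subtracted, without pairs of libraries and by the split on the second principal component were added after seeing the data, and the called lists were taken up for full account after their results were seen. The number of genes called stayed within 1.5 times its value except within corpuscles 4 and 5 and skin 5 and 6 (5290, fewer libraries), and leaving out each library gave 7516 to 9011. The main fit had 4826 higher and 3437 lower, limma-voom 4420 and 4209, and the fit within corpuscles 4 and 5 and skin 5 and 6 3776 and 1514. The number over 2-fold was 4772 with a 5 CPM filter (fewer genes tested) and 4571 in a test against a fold of 2 (a stricter hypothesis), with 6885 to 7554 on leaving out each library. Of 94 named genes 71 kept call and direction under every alternative run. Upper-quartile factors moved the median log2 fold change of all genes by 0.15. The replicate numbers did not pair the samples (correlations of same-numbered libraries 0.08, 0.08, 0.05, -0.18 and 0.20), and the replicate block called 7005 genes, or 6729 with a length correction. The higher number of genes detected in corpuscles was 80.4 at a 5 CPM minimum (exact permutation p = 0.909).

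Camera called 13 lists (11 to 13 on leaving out each library), 0 with an estimated correlation (6 at an unadjusted p under 0.05), while fry called 20 and its mixed form 23, tests of another hypothesis. With an estimated correlation the adjusted p was 0.218 for sensory neuron, 0.104 Merkel, 0.172 potassium channel, 0.228 receptor, 0.0853 synaptic, 0.0748 junction, 0.101 basement membrane, 0.461 keratinocyte, 0.173 fibroblast, 0.101 endothelial, 0.0587 oxidative phosphorylation, 0.562 ribosomal and 0.531 cell cycle genes; correlation within the lists is what that setting changes. For the adjusted p-values and gene values that follow the cause was not tested.

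Keratinocyte genes lost their call with a 5 CPM filter (0.0937), limma-voom (0.0543), length correction (0.0521), thinning (0.0788), background subtraction (0.0556), without corpuscles 4 and 5 (0.109) and within corpuscles 1 to 3 and skin 1 to 4 (0.0615), and leaving out each library gave 0.0200 to 0.0700. Cell cycle genes lost theirs with a 5 CPM filter (0.229), DESeq2 (0.0760), thinning (0.103), background subtraction (0.205), without corpuscles 4 and 5 (0.118) and within corpuscles 1 to 3 and skin 1 to 4 (0.149), and leaving out each library gave 0.0104 to 0.125. Sensory neuron genes lost theirs with limma-voom (0.0585) and within corpuscles 4 and 5 and skin 5 and 6 (0.162), receptor genes with a 5 CPM filter (0.308) and background subtraction (0.205), and potassium channel genes with background subtraction (0.0832).

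Lists without a call turned direction. Mechanosensitive genes did so with length correction (0.981), the block with length correction (0.925), without skin 5 and 6 (0.871), within corpuscles 4 and 5 and skin 5 and 6 (0.890), with fry (0.529), without corpuscle 1 (0.964) and without corpuscle 3 (0.869); leaving out each library gave 0.691 to 0.971. Leukocyte genes did with fry (0.551), within corpuscles 4 and 5 and skin 5 and 6 (0.358), without corpuscle 1 (0.964) and without corpuscle 3 (0.971); leaving out each library gave 0.589 to 0.987. Melanocyte genes did with a 5 CPM filter (0.731), without corpuscles 4 and 5 (0.478), within corpuscles 1 to 3 and skin 1 to 4 (0.479), with the split as a covariate (0.990), without corpuscle 4 (0.698) and without skin 2 (0.880); leaving out each library gave 0.497 to 0.973. Neural crest genes did without a filter (0.998) and within corpuscles 4 and 5 and skin 5 and 6 (0.494), as did early response genes there (0.968).

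Within corpuscles 4 and 5 and skin 5 and 6 (fewer libraries) the log2 fold changes of genes that lost their call were -0.68 for CACNA1C, -1.61 CACNA1G, -0.95 CCNE2, 2.07 CD4, 0.68 ETS1, 2.08 FOS, 0.81 GRIA2, 3.39 KCND2, -1.10 KIF23, -1.55 MYH11, -0.55 PIEZO1 and -1.59 TPX2. In that fit Schwann cell genes (0.0367) and erythroid genes (0.0277) gained a call, as early response genes did with a 5 CPM filter (0.0245) and background subtraction (0.0318). CACNA1D lost its call with the block (adjusted p = 0.0855), the block with length correction (0.0629), background subtraction (0.0803), without skin 5 and 6 (0.163) and within corpuscles 1 to 3 and skin 1 to 4 (0.133). TPX2 also lost its call with background subtraction (0.0603), and MBP within corpuscles 1 to 3 and skin 1 to 4 (0.0589).

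Log2 fold changes of genes without a call turned sign. CACNA1E was at 0.046 with upper-quartile factors, 0.184 with a 5 CPM filter, 0.027 with the block and length correction, 0.0536 with length correction, 0.0596 thinned, 0.143 without corpuscles 4 and 5, 0.279 within corpuscles 1 to 3 and skin 1 to 4, and from -0.415 to 0.0474 on leaving out each library. CACNA2D1 was at -0.126 with limma-voom, -0.0357 with the block, -0.0632 without corpuscles 4 and 5, -0.0811 within corpuscles 1 to 3 and skin 1 to 4, and from -0.0323 to 0.511 on leaving out each library. CACNB4 was at 0.152 within corpuscles 1 to 3 and skin 1 to 4, and at -5.02 and called (adjusted p = 0.0177) within corpuscles 4 and 5 and skin 5 and 6. NALCN was at -0.0909 in that last fit, and at 0.724 and called (adjusted p = 0.0246) without corpuscles 4 and 5.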

Other observations

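The genes below were chosen after their values were seen. Coagulation factor XIII (F13A1) was at 13809 ± 14022 CPM (SD, n = 5) against 442 ± 107 CPM (n = 6) in skin, a log2 fold change of 4.96 ± 0.82 (edgeR adjusted p = 0.000195). It was at 17113, 15226 and 34836 CPM in corpuscles 1 to 3 and at 812 and 1060 CPM in corpuscles 4 and 5. TAC1, the precursor of substance P, was at 3459 ± 2085 CPM against 102 ± 29.5 CPM (5.08 ± 0.42), and PLS1, an actin-bundling protein, at 1902 ± 1185 CPM against 47.1 ± 12.5 CPM (5.34 ± 0.40). GFRA2, a receptor of the GDNF family, was at 905 ± 553 CPM against 102 ± 17.3 CPM.

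POLR2A, the large subunit of RNA polymerase II, was at 2.61 ± 1.37 CPM in corpuscles and 96.9 ± 15.0 CPM in skin (log2 fold change -5.22 ± 0.41), and the splicing factor HNRNPL at 8.01 ± 4.06 CPM and 112 ± 12.7 CPM. Whether a bias by GC content lowered their counts in corpuscles was not tested, since no genome sequence was used here. Shorter genes were higher in corpuscles on the whole, with a median log2 fold change of 0.80 in the shortest of 5 length groups and -0.21 in the longest.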
